A study of Mus musculus with 22 samples.

How the data were processed

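Whole pancreas of C57Bl/6 dams and newborn pups was profiled with a TempO-Seq mouse whole transcriptome panel on an Illumina NextSeq, per the labels' protocols. Female mice were injected 2 times per week with corn oil or 20 ng/kg per day TCDD. Reads were converted with bcl2fastq 2.17.1.14, per the submitters' processing notes; the aligner and genome build are not given in the sources used here, and no coordinates are printed. The authors deposited 1 table of raw counts per probe, with no normalization per the labels or the file header, for 30146 probes and 22 libraries. The values were whole numbers, with library totals of 11223816 to 34911410. Probes are named by gene symbol and number, and 6290 of the 21450 symbols have more than 1 probe. Of these symbols, 21312 were current in the reference gene table, 35 were known there only as synonyms and 103 were unmatched. The symbols are used as the table gives them. No molecular identifiers are described, so counts are reads and not independent molecules, and floors (3 counts of a library's total) cover counting error only. A probe covers a short stretch of a transcript, so near-identical genes such as those of the amylase, elastase, REG and cytochrome P450 families can share signal, and values for their members are uncertain.

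Samples were grouped by the labels for stage, sex and chemical, and no sample was moved or left out of the comparisons reported as main results. The labels' numbers tie each dam to its litter and the male to the female pup of a litter. Replicates of a group are separate animals. No pair of libraries of 1 group agreed within sampling noise (lowest chi-square per degree of freedom 7.47). As a label check, CPM (counts-per-million of the library total) of stage and Y-linked genes was read in each library. Afp, Pnlip and the Y-linked genes were in lists fixed before the data were examined. The rule was set afterwards, with stage read as Afp above or below Pnlip and Y-linked genes as present from 10 CPM for the sum of 4 genes. It put 13 libraries against their labels. The number of matching libraries was set against 100000 shuffles of the labels over the libraries (one-sided permutation test).

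Tests were fitted in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment, threshold 0.05). Fits of a TCDD effect held the libraries of that comparison alone. For the litter comparison the counts of the 2 pups of a litter were summed before the fit, giving 3 litters against 4. Sex difference, male against female and dam-litter difference used group-means models with contrasts. Fold changes are on the log2 scale after TMM and ± gives the model's standard error, while CPM values use the total count with no TMM factor and ± gives the SD. Values in the comparisons are of single probes, and CPM in the check of the labels are sums over the probes of a gene. The 2 scales can differ where a few abundant probes differ between groups. Gene lists (43, of which 18 are cell type markers and 25 pathways, each with at least 5 measured members to be tested) were fixed before the data were examined and tested with camera in limma 3.58.1 with an estimated inter-gene correlation, adjusted over the lists of a comparison. Of these, the acinar cell, beta cell, AhR battery, circadian clock, REG protein and pancreatitis, cell cycle and sex chromosome lists are described. Named genes followed a rule set beforehand: the 12 largest and 12 smallest log2 fold changes among passing probes with a mean count of at least 10 in the higher group, or the 8 smallest p where fewer than 5 probes passed (4 for the interactions), a fixed set of AhR, islet, acinar and clock genes, and up to 4 members of the main lists. Sex-linked and stage genes of the label check were named for that check.

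The fit and list functions were tested on simulated counts with the real library sizes, dispersions and 1 mean per probe over the libraries. In each set 200 probes were changed, drawn only among those well above the low-count filter, and 1 list was shifted. The simulated libraries held no split by Afp and Pnlip. The recovery rates below therefore do not hold for probes with few counts, nor as the power of the real groups. With 1 simulated set, false calls in 1 case exceeded the bound set for the test, and 10 seeded sets were then averaged with the bound unchanged. At a log2 change of 1.5 the test recovered 34.4% of changed probes for the dams, 48.1% for the female pups, 26.2% for the male pups, 97.8% for the litters, 15.0% for the sex difference, 26.4% for the dam-litter difference, 82.2% for male against female pups and 42.1% for pups against dams. At a log2 change of 3 it recovered 90.8%, 93.8%, 88.4%, 100%, 76.6%, 83.8%, 96.7% and 92.2%. Mean false calls lay between 3.40 and 6.49% of calls.

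The numbers of the labels mark shared litters, so fits with the litter number as a block were made for the sex difference, male against female pups and pups against dams. A block of dam and litter number for the dam-litter difference, over the 7 numbers that both hold, and scalings of the litters by total counts with no TMM factor, over all probes and without the 50 or 100 most abundant, were added after seeing the data. As a check, deviations from the group means were correlated between pups. Those of the 7 same-numbered pairs correlated at -0.827 to 0.0191 (median -0.445), with 0 of 7 over 0.1, and those of 18 pairs with different numbers at -0.630 to 0.705, with 6 over 0.1.

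Alternatives fixed beforehand were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, probes summed per gene, removal of the 20 most abundant probes, larger fits, the litter block, pup-level fits with the litter ignored or as a random effect, camera with a preset correlation of 0.01, fry, and leaving out each replicate. Fits without the libraries whose stage genes, or stage or sex genes, went against the label were added after seeing the data. Other splits of the samples into groups of the same sizes were all fitted, or 100 drawn where there were more. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.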

Results

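Gene expression in whole pancreas was measured in 22 libraries from C57Bl/6 mouse dams and their newborn pups with TempO-Seq, a targeted assay in which pairs of detector oligonucleotides are ligated on their transcript and counted by sequencing. Dams had received injections of corn oil, the control, or of TCDD, a dioxin that activates the aryl hydrocarbon receptor (AhR), at 20 ng/kg per day from before mating until birth. The labels gave 4 control dams, 4 TCDD dams, 3 control and 4 TCDD female pups, and 3 control and 4 TCDD male pups, with 1 pup of each sex from each of 7 litters. The replicate number used here is the number of the dam or litter in the labels. The table held 30146 probes for 21450 gene symbols. Total counts ranged from 11223816 to 34911410 per library (median 16205307.5), and 17614 to 26420 probes had at least 1 count. The 20 most abundant probes took 45.7 to 69.7% of the counts. A floor of 3 counts corresponded to 0.0859 to 0.267 counts-per-million (CPM), which covers counting error only.

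Genes that mark the stage of the animal went against the label in 8 of the 22 libraries. Afp, a fetal plasma protein, and Pnlip, the triglyceride lipase of the mature exocrine pancreas, split the libraries without intermediates, with CPM summed over the probes of a gene. In 14 libraries Afp stood at 468 to 1487 CPM with Pnlip at 22.3 to 91.6 CPM. In the other 8, Afp stood at 0 to 1.25 CPM and Pnlip at 40765 to 48925 CPM. Afp was above Pnlip in the libraries labelled control dam 4, control dam 2, TCDD dam 10 and TCDD dam 6. Pnlip was above Afp in those labelled TCDD female pup 6 and TCDD male pups 11, 8 and 10. Dlk1 and Igf2, imprinted genes of fetal growth, divided the libraries in the same way, at 387 to 644 and 80.2 to 151 CPM where Afp was above Pnlip and at 0.064 to 1.19 and 0.0581 to 0.781 CPM elsewhere. The islet hormone genes Ins1 (insulin) and Gcg (glucagon) stood at 204 to 521 and 87.0 to 274 CPM in the Afp-rich libraries and at 11.8 to 77.8 and 6.58 to 45.5 CPM in the others. Cpa1, a digestive carboxypeptidase, stood at 16807 to 24825 and 34094 to 41025 CPM.

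**Figure D1:**
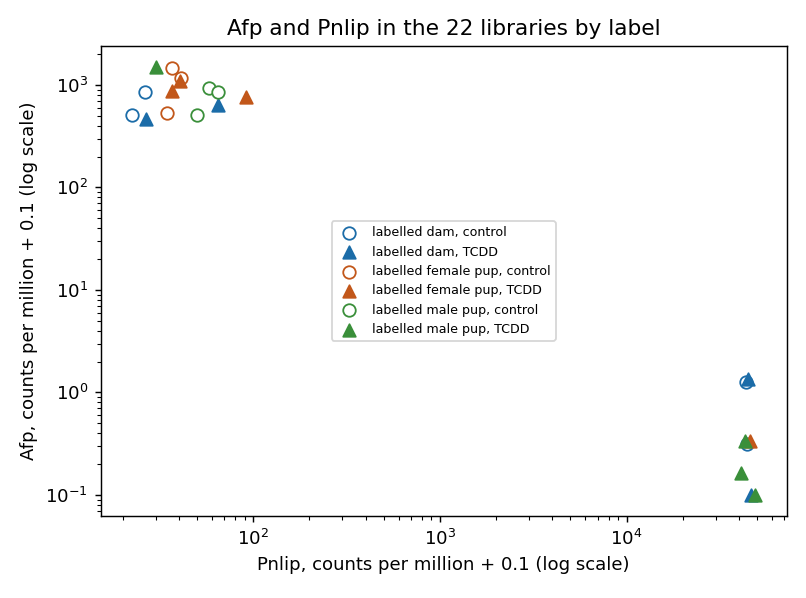
Afp against Pnlip in each of the 22 libraries, in CPM plus 0.1 on log axes, with colour and symbol giving the label of the library. Each point is 1 library. The 14 libraries at the upper left include 4 labelled dams, and the 8 at the lower right include 4 labelled pups.

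Y-linked transcripts went against the label in 10 libraries. Ddx3y, Kdm5d, Eif2s3y and Uty, which lie on the Y chromosome, summed to 64.3 to 89.3 CPM in 7 libraries and to 0 to 1.05 CPM in the other 15. They were present in the libraries labelled control dam 4, TCDD dam 6, control female pups 2 and 7 and TCDD female pup 11. They were at 0 or near it in those labelled control male pups 4 and 2 and TCDD male pups 11, 8 and 10. No library combined Y-linked transcripts with Pnlip above Afp. With both checks, 13 libraries went against their label (6 of 10 labelled control and 7 of 12 labelled TCDD), and 9 did not. The class sizes equalled those the labels call for: 8 libraries with high Pnlip and no Y-linked transcripts, 7 with high Afp and Y-linked transcripts, and 7 with high Afp alone. All groups below are therefore groups of libraries as labelled, and each direction holds for the labels only. Neither Afp, Pnlip nor the Y-linked genes can show whether the treatment labels are right.

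**Figure D2:**
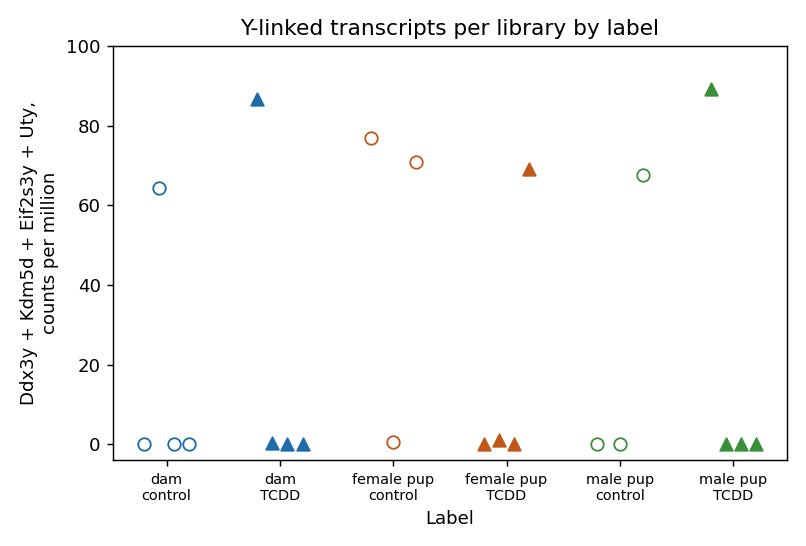
Summed CPM of Ddx3y, Kdm5d, Eif2s3y and Uty in each library, on a linear axis from 0, by label. Circles are libraries labelled control and triangles are libraries labelled TCDD. The 7 libraries above 60 CPM include 2 labelled dams and 3 labelled female pups.

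Cyp1a1, Cyp1a2, Cyp1b1 and Ahrr, all AhR targets, lay near the detection floor. Cyp1a1, the cytochrome P450 gene most strongly induced through AhR, had 0 to 29 counts per library over its 3 probes, with the highest value in the library labelled TCDD female pup 6. Cyp1a2 had 0 to 17 counts, Cyp1b1 0 to 27 and Ahrr, which encodes the AhR repressor, 0 to 3. Cyp1a1, Cyp1a2 and Ahrr were under the low-count filter in the dam, female pup, male pup and litter comparisons. Tiparp, an AhR target that ADP-ribosylates proteins, had 19 to 382 counts, and Nqo1, a quinone reductase, had 0 to 67. Members of the AhR battery list were counted by 1 probe each, the one with the highest mean count. Adjusted over all probes, 0 passed in the dams (17 measured), female pups (21), male pups (18) or litters (21). Another probe of Gstp1, a member, was called higher in the litters, with a log2 fold change of 0.54. It lay at -0.13 without the labelled pups that had Pnlip above Afp. Adjusted over the list alone, 1 member was higher in the litters and 0 passed in the other groups. The list as a whole had an adjusted p of 0.980, 0.663, 0.480 and 0.701 in these comparisons.

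The effect of the TCDD label on newborn pancreas was tested with the counts of the male and female pup summed per litter, 3 control litters against 4. Transcripts of digestive enzymes were higher in the litters labelled TCDD. Each of these 4 litters held exactly 1 library with Pnlip above Afp, and 0 of the 3 control litters held any. By 1 of its 2 probes, Pnlip stood at 20.7 ± 1.41 CPM (SD, n = 3) in control litters and 11087 ± 1390.3 CPM (SD, n = 4) in TCDD litters, a log2 fold change of 9.59 ± 0.171 (SE; adjusted p = 2.94e-15). This SE and those below are of litter sums and do not measure the spread between pups. The median SE of the called probes was 0.135 for the sums. With the 14 pups as samples it was 0.307 (litter as a random effect) and 0.446 (litter ignored), and 0 probes passed. By Y-linked transcripts the sums were not of 1 male and 1 female in litters 4, 8 and 10, which lacked them in both libraries, and 7, which had them in both. Ctrl, a chymotrypsin-like protease, rose by 3.54 ± 0.114 on the log2 scale, Ctrc (chymotrypsin C) by 4.45 ± 0.20, Cela1 (elastase) by 2.44 ± 0.0951, Pla2g1b (pancreatic phospholipase A2) by 3.36 ± 0.240, Zg16, a zymogen granule protein, by 1.81 ± 0.0938 and Cpa1 by 1.12 ± 0.0872 (largest adjusted p of these, 1.05e-06). Cela3a stood at 0.137 ± 0.104 CPM in control and 2.05 ± 1.37 CPM in TCDD litters (adjusted p = 0.00112). The 28 measured genes of the acinar cell list were counted by 1 probe each. Over all probes 23 were higher and 0 lower, and adjusted over the list alone 25 were higher and 1 lower. Prss1, a member, had a called probe at a log2 fold change of 0.63 and another at -0.54. The list passed its test with an estimated correlation (adjusted p = 0.00271, median log2 fold change 0.86). Without the 4 Pnlip-rich libraries it did not pass (adjusted p = 0.963, median log2 fold change -0.14), and Pnlip, Ctrl, Ctrc, Cela1 and Cpa1 lay at log2 fold changes of -0.040, -0.050, -0.13, -0.22 and -0.11.

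REG proteins, small secreted lectins that rise in pancreatitis and regeneration, were also higher in these litters, though not without the same 4 libraries. Reg2 stood at 3.02 ± 0.905 CPM in control litters and 1177 ± 803 CPM in TCDD litters, a log2 fold change of 9.16 ± 0.548. The log2 fold changes of Reg3a, Reg3b, Reg3d and Reg1 were 6.29 ± 0.827, 4.38 ± 0.760, 2.76 ± 0.218 and 1.36 ± 0.0982. Of the 12 measured members of the REG protein and pancreatitis list, 6 were higher over all probes, and 8 were higher and 1 lower adjusted over the list alone (list adjusted p = 0.0444 with an estimated correlation, median log2 fold change 1.26). Without litter 2, 4, 7, 11 or 6 the list did not pass (adjusted p = 0.0804 to 0.176). Without the 4 Pnlip-rich libraries it had an adjusted p of 0.963 and a median log2 fold change of -0.10, and Reg1, Reg2, Reg3a, Reg3b and Reg3d lay at -0.45, -0.21, -0.12, -0.059 and -0.48. Among other genes, Fgf21, a metabolic hormone, rose by 3.83 ± 0.368 on the log2 scale, Nfasc, a cell adhesion molecule, by 3.43 ± 0.729 and Nat8f5 by 3.65 ± 0.772. Without the 4 Pnlip-rich libraries Nfasc lay at 0.10. Another called Fgf21 probe went from 3.43 to 0.048. Ranbp3l stood at 0.0897 ± 0.0825 CPM in control and 0.993 ± 0.423 CPM in TCDD litters (adjusted p = 0.00396).

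Among genes lower in the litters labelled TCDD, each of which held 1 Pnlip-rich library, were several of cell division. Top2a, a member of the cell cycle list, stood at 75.2 to 233 CPM in the Afp-rich libraries, summed over its probes. In the Pnlip-rich ones it stood at 3.20 to 34.9 CPM. An effect of the TCDD label on the genes of cell division therefore cannot be told apart from that composition of the sums. Ccnb2, a mitotic cyclin, had a log2 fold change of -0.78 ± 0.138, Cenpa, the centromeric histone, -0.69 ± 0.153, Cip2a, an inhibitor of protein phosphatase 2A, -0.94 ± 0.215, and Pimreg, a mitotic regulator, -0.86 ± 0.183. Values for Zp3, an egg coat glycoprotein, Pipox, a peroxisomal oxidase, Peg10, an imprinted gene, Anxa2, a membrane-binding annexin, Klhl13 and Fam183b were -0.90 ± 0.206, -0.87 ± 0.137, -0.78 ± 0.187, -0.73 ± 0.110, -0.72 ± 0.151 and -0.70 ± 0.161. Slc15a1, a peptide transporter, and Slc9b2 stood at 0.929 ± 0.620 and 0.448 ± 0.121 CPM in control litters and at 0.0714 ± 0.0739 and 0.0296 ± 0.00289 CPM in TCDD litters (adjusted p = 0.0404 and 0.0224). Of the 32 measured members of the cell cycle list, counted by 1 probe each, 3 were lower over all probes and 8 adjusted over the list alone. The list itself did not pass (adjusted p = 0.521 with an estimated correlation). With any probe of a gene counted, Ccnb2, Cenpa, Birc5 and Ccna2 were members with a called lower probe, the last 2 at -0.56 and -0.57.

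Islet and clock genes mostly did not pass in the litters. Log2 fold changes were -0.40 ± 0.175 for Ins1, -0.40 ± 0.143 for Ins2 and -0.45 ± 0.161 for Gcg (adjusted p = 0.317, 0.20 and 0.20). Of the 16 measured members of the beta cell list, 1 passed over all probes, Ero1lb, an oxidase of disulfide bond formation (0.82 ± 0.0969), and 2 were higher and 1 lower adjusted over the list alone (list adjusted p = 0.958; median log2 fold change -0.05 and mean 0.06, of opposite sign). Of the 18 measured circadian clock genes, Clock alone passed, both over all probes and adjusted over the list alone, with a log2 fold change of 0.51 ± 0.101 (list adjusted p = 0.235). Clock stood at 30.02 ± 2.79 and 29.9 ± 2.75 CPM, so this difference arose with the scaling factors, which were 1.21 to 1.25 in control and 0.813 to 0.912 in TCDD litters. Dbp, Per1, Arntl, Tiparp, Nqo1 and Cyp1b1 had log2 fold changes of 0.59, 0.69, -0.08, 0.05, -0.06 and 1.04, none past the threshold.

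In all, 340 of 18578 probes passed between the litters at an adjusted p under 0.05 with edgeR, 281 higher and 59 lower in TCDD litters, for 239 and 55 genes. DESeq2 called 609 (435 higher, 174 lower) and limma-voom 329 (261 higher, 68 lower). With the 14 pups as samples 0 passed, with the litter as a random effect or ignored, and without control litter 2, 4 or 7 the count was 139, 185 or 155. Without the 4 pup libraries with Pnlip above Afp, 0 probes passed with edgeR (819 at an unadjusted p under 0.05; other tools were not run on this subset), 0 lists passed, and the median log2 fold change of the called probes, in the direction of the call, went from 0.77 to 0.083. This fall was mainly that of the higher probes. For the 272 higher probes tested again the median log2 fold change went from 0.83 to 0.028, with 146 still above 0 and 17 at 50% of their fold or more. For the 57 lower probes it went from -0.58 to -0.28, with all 57 still below 0 and 25 at 50% of their fold or more. These libraries were left out for their Pnlip, so the fall of Pnlip and of genes that vary with it is not independent of that choice. Among the lower probes, Ccnb2, Cenpa, Cip2a, Pimreg, Zp3 and Pipox then lay at log2 fold changes of -0.56, -0.43, -0.89, -0.49, -0.56 and -0.56. The signs of the lower probes are not independent evidence either, since the calls that picked them used the 10 remaining libraries too. In this refit each TCDD-labelled litter was 1 library, set against control sums of 2. Leaving out libraries whose stage or sex genes went against the label, 324 of the called probes were tested. Their median log2 fold change in the direction of the call was 0.0023, with 50.3% keeping their sign.

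**Figure D3:**
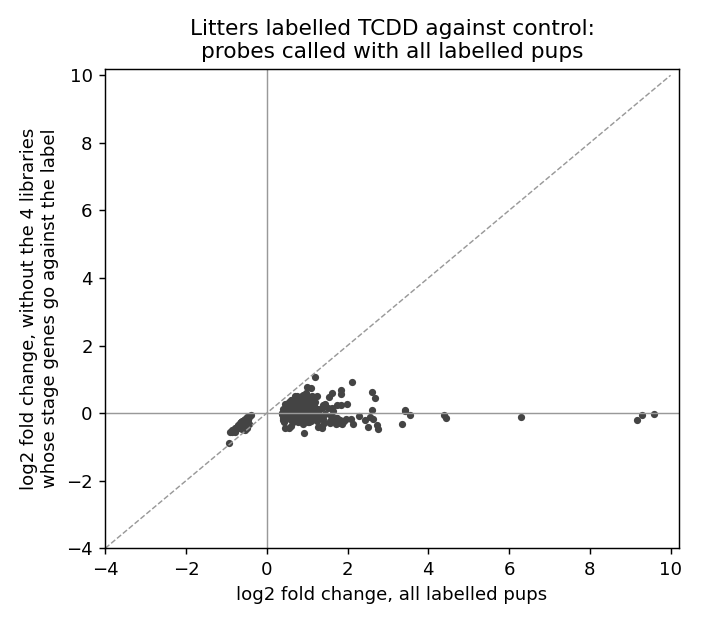
Log2 fold changes between litters labelled TCDD and control for the called probes that were tested in both fits, with all labelled pups on the horizontal axis and without the 4 pup libraries with Pnlip above Afp on the vertical axis. Each point is 1 probe and the dashed line marks equal values. On the vertical axis the higher probes have a median of 0.028, and the lower probes, all below 0, a median of -0.28.

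In the dams, no gene passed between the 4 libraries labelled control and the 4 labelled TCDD. The genes with the smallest unadjusted p were Banp, a nuclear matrix protein, with a log2 fold change of -0.76 ± 0.196, Bri3bp (1.34 ± 0.366), Ccl6, a chemokine (1.78 ± 0.507), Wnk2, a kinase (-1.13 ± 0.347), Senp8 (-0.82 ± 0.251), Naa60 (1.96 ± 0.623), Picalm (0.50 ± 0.159) and Ddit4 (0.92 ± 0.300), each with an adjusted p of 1.0. By 1 of its 2 probes, Pnlip stood at 10533 ± 12165 CPM (SD, n = 4) in control and 11445 ± 13225 CPM (SD, n = 4) in TCDD dams. Ins1, Ins2 and Gcg had log2 fold changes of -0.07 ± 0.672, -0.10 ± 0.520 and 0.24 ± 0.569, and Tiparp and Nqo1 of 0.39 ± 0.321 and 0.67 ± 0.698. The acinar cell, beta cell and circadian clock lists had 0 members past the threshold, over all probes or adjusted over the list alone (list adjusted p = 0.997, 0.997 and 0.727). Of 15594 probes, 0 passed with edgeR, 150 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 and 0. In each of the 2 dam groups, 2 of the 4 libraries had Afp above Pnlip.

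In the female pups, no gene passed between 3 control and 4 TCDD libraries. The smallest unadjusted p values were those of Ptma, prothymosin alpha (log2 fold change 1.25 ± 0.302), Trim50, a ubiquitin ligase (-2.25 ± 0.57), Zbtb49 (1.57 ± 0.429), Ppm1d, a phosphatase induced by p53 (-1.09 ± 0.304), Noxa1 (-0.61 ± 0.170), Xlr3b, an X-linked gene (-1.03 ± 0.292), Hmgxb3 (1.40 ± 0.399) and Mansc1 (0.78 ± 0.223), each with an adjusted p of 0.996. Pnlip had a log2 fold change of 9.67 ± 3.51 and Ctrl of 3.61 ± 1.53, neither past the threshold. Only the library labelled TCDD female pup 6 had Pnlip above Afp in these groups. Ins1, Ins2 and Gcg had log2 fold changes of -0.26 ± 0.556, -0.41 ± 0.49 and -0.53 ± 0.530. The acinar cell, beta cell and circadian clock lists had 0 members past the threshold over all probes or adjusted over the list alone (list adjusted p = 0.663, 0.725 and 0.663). Of 17513 probes, 0 passed with edgeR, 299 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 and 0.

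In the male pups, no gene passed with edgeR between 3 control and 4 TCDD libraries, although 2703 of 16176 probes had an unadjusted p under 0.05. Those with the smallest p were Sgk1, a kinase induced by glucocorticoids (log2 fold change 2.21 ± 0.379), Slc6a15, an amino acid transporter (2.80 ± 0.496), Retreg1, a receptor for autophagy of the endoplasmic reticulum (3.36 ± 0.615), Lifr, a cytokine receptor (2.36 ± 0.433), Asb11 (1.97 ± 0.367), Trp53inp1 (1.58 ± 0.299), Arl5b (2.24 ± 0.433) and Gnmt, a methyltransferase (2.36 ± 0.460), each with an adjusted p of 0.273. Pnlip, Amy1 (amylase) and Ctrl had log2 fold changes of 10.93 ± 2.44, 3.00 ± 0.608 and 5.36 ± 1.25, and Ins1, Ins2 and Gcg of -1.36 ± 0.408, -1.32 ± 0.358 and -1.15 ± 0.499. Over all probes, 0 members of the acinar cell, beta cell or circadian clock list passed. Adjusted over the list alone, 24 of 28 acinar genes were higher and 1 lower, 2 of 13 beta cell genes were higher and 5 lower, and 2 of 15 clock genes were higher, while each list had an adjusted p of 0.480 with an estimated correlation. DESeq2 called 505 probes (414 higher, 91 lower) and limma-voom 0. Of the 4 TCDD libraries, 3 had Pnlip above Afp, and without the fourth, labelled replicate 6, edgeR called 6451 probes.

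Whether the TCDD label acted differently in male and female pups was tested as an interaction over the 14 pup libraries, with a positive value for a larger effect in males. The smallest unadjusted p values were those of Krt78, an epithelial keratin (3.85 ± 0.931), Slc25a42, a mitochondrial carrier (3.15 ± 0.776), Trim50 (4.27 ± 1.06) and Hnrnpa0, an RNA-binding protein (-0.93 ± 0.235), each with an adjusted p of 0.876. Pnlip had an interaction of 1.69 ± 3.06 and Ins1 of -1.12 ± 0.758. Of 17924 probes, 0 passed with edgeR, 666 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 and 0. Without litter 6, whose 2 pups both went against the other TCDD libraries of their sex in Afp and Pnlip, 5510 probes passed. The TCDD male libraries left then all had Pnlip above Afp, and all female libraries left had Afp above Pnlip. This count is therefore not evidence that the effect differs by sex.

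The difference between the effect in litters and in dams was tested in the same way, with a positive value for a larger effect in litters. Bri3bp (-1.67 ± 0.387), Usp36, a deubiquitinase (1.72 ± 0.426), and Cdk17, a kinase (0.74 ± 0.187), had the smallest unadjusted p, with adjusted p values of 1.0. So did Cd244a, an immune receptor at 0 counts in all control dams, for which no fold is given. Pnlip had a difference of 9.08 ± 3.57 that did not pass. Of 19054 probes, 0 passed with edgeR, 556 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 and 0. This model did not pair each dam with its litter.

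Male and female pups, compared over the mean of both treatments, showed no passing difference in the Y-linked genes. Ddx3y, Kdm5d, Eif2s3y and Uty, examined here because they check the labels, had log2 fold changes of -0.26 ± 1.46, -0.46 ± 1.40, 0.08 ± 1.24 and -0.43 ± 1.46. Of the 8 measured members of the sex chromosome list, 0 passed over all probes or adjusted over the list alone (list adjusted p = 0.692; median log2 fold change 0.03 and mean -0.04, of opposite sign). The smallest unadjusted p values were those of Krt78 (2.05 ± 0.47), Uggt1, a glycoprotein folding sensor (0.87 ± 0.220), Tfg (0.62 ± 0.169), Invs (-2.13 ± 0.597), Rerg (-1.81 ± 0.509), Rexo2 (1.12 ± 0.317), Pdia6, a disulfide isomerase (0.68 ± 0.194), and Smdt1 (0.65 ± 0.190), each with an adjusted p of 0.895. Of 17924 probes, 0 passed with edgeR, 665 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 and 0. Without litter 6, 5638 probes passed. The TCDD male libraries left then all had Pnlip above Afp and lacked Y-linked transcripts, while all female libraries left had Afp above Pnlip. This count is therefore not evidence of a sex difference.

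Control female pups and control dams were compared to see the stage difference without TCDD. Pnlip, Ctrl, Cela1 and Zg16 had log2 fold changes of -10.85 ± 3.29, -4.48 ± 1.48, -3.50 ± 1.22 and -2.89 ± 1.07 in pups, none past the threshold (adjusted p = 0.783). The smallest unadjusted p values were those of G6pc, the glucose-6-phosphatase of gluconeogenesis (3.03 ± 0.668), Stx16 (-0.83 ± 0.187), Tnni2, a muscle troponin (3.10 ± 0.795), Atg4b (1.81 ± 0.469), Cd177, a neutrophil surface protein (2.62 ± 0.686), Clcn5 (-1.22 ± 0.321), Dtnbp1 (0.90 ± 0.238) and Derl1 (-0.71 ± 0.190). The acinar cell list had 0 of 28 members past the threshold and an adjusted p of 0.609. Of 16367 probes, 0 passed with edgeR, 707 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 3 and 0. Of the 4 control dams, 2 had Afp above Pnlip, and without them 4633 probes passed, a count that is not independent evidence of a stage difference, since the libraries were left out for their stage genes.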

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

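The tests of label shuffling, mixed RNA, altered maturation, the Pnlip-rich libraries and the scaling, and the counts over other splits of the samples, were chosen after the results they bear on were seen. A library stood apart from the other 3 of its group by Dixon's criterion in 20 of 64 sets of 4 values examined. Chance flags about 1 in 20 groups. With CPM summed over the probes of a gene, the library labelled TCDD male pup 6 stood apart in 8 values: Afp at 1487 CPM, Pnlip at 29.9 CPM, Y-linked genes at 89.3 CPM, Tiparp at 18.3 CPM, Ins1 at 320.3 CPM, Ins2 at 714 CPM, Gcg at 222 CPM and a share of 45.8% of counts in the 20 most abundant probes. The other 3 libraries of its group had Pnlip above Afp. Tiparp followed this division in all groups, at 9.77 to 18.3 CPM in Afp-rich libraries (16.6 CPM in control female pup 2) and 1.24 to 3.77 CPM in Pnlip-rich ones. The library labelled TCDD female pup 6 stood apart in 4, with Pnlip at 45533 CPM, Cpa1 at 41025 CPM, Cyp1a1 at 1.71 CPM and 18342 probes detected. Y-linked genes stood apart at 64.3 CPM in the library labelled control dam 4, 86.6 CPM in that labelled TCDD dam 6 and 69.1 CPM in that labelled TCDD female pup 11. Control dam 4 also had the highest total count, 34911410. Values near the floor stood apart for Cyp1a2 (0.830 CPM, TCDD female pup 10) and Ahrr (0.0286 CPM in control dam 4, 0.111 CPM in TCDD dam 6 and 0.157 CPM in TCDD female pup 8).

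Stage and sex genes went against the label in 13 of 22 libraries. Mixing of dam and pup RNA is argued against, since the highest Afp among Pnlip-rich libraries was 0.266% of the lowest value among the Afp-rich ones. Altered maturation under TCDD is argued against for the libraries labelled control dam 4 and TCDD dam 6, with Y-linked transcripts at 64.3 and 86.6 CPM. It is also argued against for the 3 libraries labelled TCDD male pup with Pnlip above Afp, since all 3 lacked Y-linked transcripts. The libraries labelled control dam 2 and TCDD dam 10 lacked Y-linked transcripts. That 2 control-labelled dams had Afp above Pnlip argues against altered maturation in dams only if their control labels are right. Altered maturation was not decided for the library labelled TCDD female pup 6. Pnlip was above Afp in 1 of 4 TCDD-labelled and 0 of 3 control-labelled female pups, too few to decide (Fisher's exact test, two-sided p = 1.0). In this library Afp, Dlk1 and Igf2 stood at 0.236, 0.413 and 0.295 CPM. It correlated at 0.934 to 0.961 with the other Pnlip-rich libraries and at 0.760 to 0.801 with the Afp-rich ones. This profile was that of the other Pnlip-rich libraries, but it rests on 1 library. Y-linked transcripts were present in 2 libraries labelled dam and 3 labelled female pup, and lacking in 5 labelled male pup. These values argue that the 10 libraries do not carry the label of their animal. How far labels and libraries were paired without regard to the animal stays open. The 9 libraries that match compare with 7.36 for shuffled labels (one-sided permutation p = 0.3035), which cannot show that the pairing was random. The class sizes equal those the labels call for. The control and TCDD labels may then be wrong in unknown libraries too.

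Between litters, 340 probes and 2 lists passed, and the highest of the other 34 splits of the 7 litters gave 4 probes and 1 list, with 1 and 1 of 35 splits as large as the real one. The real split was also the one that set litters holding a Pnlip-rich library against litters holding none. Its rank among the 35 splits therefore cannot tell an effect of the TCDD label from that composition. Nor does it exclude chance in how libraries were paired with the labels. Whether a few probes taking most of the counts set these calls was not decided. With total counts of all but the 100 most abundant probes and no TMM factor, most calls held. Of those still tested, 223 of 235 higher and 52 of 55 lower probes passed. Their median log2 fold changes were 0.82 and -0.58, the same as with TMM to the digits given. TMM factors there would lie between 0.983 and 1.01, and the number removed was chosen for factors near 1, so this agreement was built in. Over all probes with no TMM factor, 113 of the 281 higher and 59 of the 59 lower probes passed. Medians over all 281 and 59 were then 0.32 and -1.11. Each TCDD-labelled litter held 1 Pnlip-rich library and no control litter did, and without those libraries the median log2 fold change was 0.028 in place of 0.83 for the higher probes (median standard error 0.144 and 0.138) and -0.28 in place of -0.58 for the lower (0.121 and 0.122), with 0 called. As the libraries were left out for their Pnlip, and the remaining ones had a part in the calls, this refit alone decides nothing: the lack of Y-linked transcripts argues against a TCDD effect as the source in the 3 libraries labelled male, and for that labelled TCDD female pup 6 wrong labels and a TCDD effect cannot be told apart.

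In the other comparisons the real split gave 0 probes, so every split gave at least as many by construction and the count says nothing about chance (35 of 35 for the dams, female pups, male pups, sex difference and pups against dams, 100 of 100 for the dam-litter difference and male against female pups). The highest count of another split was 6555 probes for the dams, 3 for the female pups, 7145 for the male pups, 5142 for the sex difference, 6126 for the dam-litter difference, 5900 for male against female pups and 2 for pups against dams. For lists the real split also gave 0, with the same consequence, and the highest other values were 6 for the dams, 1 for the female pups, 6 for the male pups, 9 for male against female pups and 0 for pups against dams. Splits that call 5142 to 7145 probes where the labels call 0 point to a structure of the samples that the labels do not follow.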

How the results depend on the processing

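Fits without libraries that went against their label, the block for the dam-litter difference and the scalings by total counts were chosen after seeing the data; the other alternatives were fixed beforehand. Counts of 0 probes in the dams and in the dam-litter difference held in all alternatives fixed beforehand. The litter block changed no call: with the block 0 probes passed for the sex difference, male against female pups, pups against dams and the dam-litter difference (218, 227, 274 and 445 at an unadjusted p under 0.05), and 0 lists for male against female pups and pups against dams. The DESeq2 Wald test called 505 probes in the male pups, 609 in the litters and 3 for pups against dams. With no filter on low counts 733 probes (491 higher, 242 lower) passed between litters, 339 of them among the 340. With total counts and no TMM factor 9423 passed (119 higher, 9304 lower), Clock reached a log2 fold change of -0.0088 and Tiparp -0.48, and Ins1, Ins2 and Gcg passed as lower, since the median of all probes moved from -0.0019 to -0.52. Without the 50 and the 100 most abundant probes, where TMM factors would lie between 0.975 and 1.03, total counts gave 277 and 281. With the 14 pups as samples 0 passed, both with the litter as a random effect and with the litter ignored, where the 339 called probes tested there kept their sign. Their median log2 fold change in the direction of the call was 1.05 and 1.30 in place of 0.77, and their median SE 0.307 and 0.446 in place of 0.135. With a preset correlation 8 lists passed for the dams, 20 for the female pups, 23 for the male pups, 15 for the litters, 20 for male against female pups and 21 for pups against dams. With fry 1 passed for the male pups and 6 for the litters. The cause was not tested for the others.

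Leaving out each replicate in turn gave 0 to 6451 probes and 0 to 2 lists in the male pups (highest without TCDD replicate 6), 139 to 368 probes and 1 to 2 lists in the litters (139, 185 and 155 probes without control litters 2, 4 and 7; 1 list without litters 2, 4, 11 or 6), 0 to 5510 probes for the sex difference and 0 to 5638 probes and 0 to 6 lists for male against female pups (highest without litter 6). In the dams, female pups and pups against dams, probes and lists stayed at 0 to 0, as did probes for the dam-litter difference. Lists were not tested for the sex and dam-litter differences.

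Without libraries whose stage genes went against the label, 3 probes passed in the male pups (3 against 1 library), 0 probes and 0 lists in the litters (819 probes at an unadjusted p under 0.05), 1 probe for the dam-litter difference and 4633 for pups against dams. Leaving out those with stage or sex genes against the label as well gave 394 in the female pups (1 library against 2), 0 and 0 in the litters (714 at an unadjusted p under 0.05), 635 for the sex difference, 305 for male against female pups and 1384 for pups against dams. A lone library in these fits is assumed to vary like the others. The fit could not be made for the male pups, with 1 library against 1. Other named genes reversed only here. In the female pups without stage or sex conflicts Gcg and Ins1 had log2 fold changes of 0.94 and 1.01, and Pnlip in the sex difference -2.29. In the litters the values without stage conflicts and without stage or sex conflicts were -0.040 and -0.033 for Pnlip (its other probe -0.050 and -0.050), -0.050 and -0.12 for Ctrl, -0.22 and -0.31 for Cela1, -0.13 and -0.35 for Ctrc, -0.21 and -0.40 for Zg16, -0.21 and -0.073 for Reg2, -0.31 and -0.19 for Pla2g1b, -0.45 and -0.35 for Reg1, -0.11 and -0.20 for Cpa1, -0.48 and -0.29 for Reg3d, -0.22 and -0.33 for Ero1lb, and -0.059 and -0.0069 for Reg3b. Reg3a reached -0.12 in the former, and Clock -0.057, Nfasc -0.33, Cenpa 0.042 and Peg10 0.045 in the latter. Cyp1a1, Cyp1a2 and Ahrr had 0 to 29, 0 to 17 and 0 to 3 counts per library. They were under the low-count filter of the main dam, female pup, male pup and litter fits, which gave no test of them. Whether depth, low expression or weak probes set these counts was not tested.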

Other observations

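The test of plate order was chosen after the label conflict was seen. Across 9520 probes, pairs of libraries that were both Afp-rich correlated at 0.966 to 0.984 and pairs that were both Pnlip-rich at 0.934 to 0.977, while pairs with 1 of each correlated at 0.760 to 0.847. These are correlations across probes, which are not independent replicates.

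In the record, library names stood in alphabetical order (21 of 21 neighbouring pairs) and the 6 labelled groups formed unbroken blocks, while the number in each library name followed the wells by column in 22 of 22 libraries. A candidate explanation for the conflict is that labels were written down in the column-wise order of the plate. With the labels in record order set against the libraries in that order, 7 of 22 libraries matched in stage and sex genes, within the 95% range of 3 to 12 for shuffled labels, so this order is not the one that restores the labels. The true pairing of labels and libraries was not found.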
